A study of Mus musculus with 4 samples.

How the data were processed

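RNA from cultures of 4T1, a mouse mammary carcinoma cell line used as a model of breast cancer, was sequenced after treatment with phosphate-buffered saline (PBS) or with recombinant IL-17A (rIL17), with 2 libraries per group and 4 in all. Per the labels' protocols, libraries were made from total RNA with a strand-specific (directional) kit. The submitters' processing notes name CASAVA, HISAT2 2.0.5 and featureCounts 1.5.0-p3 and the mouse build mm10; the annotation release, the strand setting of the counting and the tool that gave the scaling factors are not given in the sources used here. Nothing in the labels says whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

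The deposited table holds 21840 genes and 1 column per library. Its unit is a normalized signal: the deposited values were never negative, and those above 0 were in general not whole numbers. Each library's values were whole multiples of 1 step (100.0% of values within 0.001 of a whole multiple). The steps, 0.9811 and 0.9944 in PBS replicates 1 and 2 and 1.0053 and 1.0029 in rIL17 replicates 1 and 2, lay next to the inverse of median-of-ratios size factors computed from the same table (1.0192, 1.0056, 0.9948 and 0.9971). The values were therefore handled as read counts that the authors had divided by 1 size factor per library, and are called normalized counts. Divided by the step, they came to 17970104 and 17511450 reads assigned to genes in the PBS libraries and 17911079 and 17715520 in the rIL17 libraries. Because the deposited values are normalized, tests made for raw counts were not used, although the recovered reads could have served for them. The test written before the data were examined for a normalized table, limma with a mean-variance trend, took their place.

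Genes with a mean of at least 1 normalized count in 1 of the groups were tested with limma 3.58.1 (R 4.3.3) on log2(normalized count + 1), with treatment as the only term and Benjamini-Hochberg adjustment, and were called at an adjusted p below 0.05. Fold changes are on the log2(normalized count + 1) scale, which understates the change of genes with low counts; errors of means are SD. Gene identifiers were matched to symbols for 21819 of 21840 rows, and coordinates are those of GENCODE M21 on mm10. The 28 gene lists were fixed before the data were examined. Of these, 27 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. They were tested again with the correlation estimated from the data and with fry. With an estimated correlation, camera also takes its degrees of freedom from the 4 libraries alone, which makes it stricter. A gene is said to have risen or fallen where it passed after adjustment over its list alone, or where the text says that it passed under the stricter filter. The named genes are Spp1, Il17ra, Il17rc, Traf3ip2 and Il17a (not analysed here), the 12 genes with the largest change in each direction among those that passed over all genes, and up to 4 members of each list with the smallest p. The second part of that rule gave 0 genes, so it was applied to the genes that passed under the stricter filter, a step chosen after the values were seen. Steap4, Nfkbiz, Tnfaip3, Lbp, Irf1, Irf7, Csf2, B2m and mt-Nd2, members of the fixed lists, are named outside the rule and were likewise chosen after their values were seen.

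The alternatives were upper-quartile scaling, no filter, a stricter filter (at least 10 normalized counts in every library of 1 group and a mean CPM of at least 1), limma-voom on the deposited values, a pseudocount of 0.1, the replicate number as a block, each library left out, mitochondrial genes left out, an adjusted p below 0.01 and limma's treat against a fold of 1.5. Robust shrinkage, total-count scaling, quantile normalization, a correction for GC content (loess of each library's log2 values on the GC content of the longest transcript, available for 99.9% of the genes passing the stricter filter) alone and with the block, and combinations with the stricter filter were added after seeing the data. The fits were tested on data simulated from these 4 libraries: over 19994 genes, the fit recovered 31% of genes changed 2-fold and 89% of genes changed 4-fold, with 0 false calls. With the stricter filter, over 12529 genes, it recovered 96% and 100%, with 6 false calls among 202. The changes were planted only in abundant genes, and genes of like abundance shared a dispersion. Genes were drawn independently, with no GC trend and no library standing apart. These rates may therefore not carry over to the real libraries. Depth of 17511450 to 17970104 reads puts 3 reads, the floor used for a count of 0, near 3 normalized counts per library. Sampling noise did not account for the spread between replicates: the chi-square statistic of the read counts per gene was 15.59 between the PBS libraries and 4.01 between the rIL17 libraries. Between the groups it was 13.87 and 9.69 for PBS replicate 1 against rIL17 replicates 1 and 2. For PBS replicate 2 it was 37.56 and 28.42. By this measure PBS replicate 1 lay closer to both rIL17 libraries than to PBS replicate 2.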

Results

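Gene expression was measured by RNA sequencing in 4T1 mouse mammary carcinoma cells treated with PBS or with recombinant IL-17A, a cytokine of T cells and innate lymphocytes that acts on epithelial cells through the receptor chains IL-17RA and IL-17RC. Each group had 2 libraries, with 17511450 to 17970104 reads assigned to genes in each. The 10 most abundant genes took 4.28% to 4.36% of each library. The comparison asks which genes of the tumor cells respond to IL-17A and, from the title of the series, whether osteopontin, encoded by Spp1, is among them.

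Of the genes known as IL-17 targets, 22 of 24 tested had more RNA in the rIL17 libraries than in the PBS libraries. Lcn2, encoding the siderophore-binding protein lipocalin-2, rose 3.36-fold, from 8473 ± 35.7 to 28464 ± 521 normalized counts (SD, n = 2 per group). Il6, encoding the cytokine interleukin-6, rose 7.80-fold from 8.89 ± 0.0844 to 76.3 ± 7.23. Mmp13, a collagenase, rose 4.12-fold from 369 ± 104 to 1496 ± 132, and the transcription factor gene Cebpd rose 2.49-fold from 960 ± 68.5 to 2387 ± 77.0. Against these, Csf1, encoding the macrophage growth factor M-CSF, fell from 10798 ± 292 to 6626 ± 137, and genes of the interferon response and of MHC class I presentation were lower as groups. The group calls by camera held at a preset correlation of 0.01 between genes. With an estimated correlation they were lost (camera adjusted p = 0.655 for IL-17 targets, 0.271 for interferon and 0.348 for MHC class I). The estimated correlations were 0.526, -0.03 and 0.022, and that form of camera also uses fewer degrees of freedom. The loss for interferon and MHC class I therefore need not come from correlation between genes. Over all genes tested, 0 single genes passed.

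Of the 24 tested IL-17 target genes, 22 were higher and 2 lower in the rIL17 libraries, with a median log2 fold change of 0.69. Adjusted over the list alone, 16 rose and 1 fell; over all genes tested 0 passed, and 12 rose under the stricter filter. Those that rose included the neutrophil-attracting chemokine genes Cxcl1 (log2 fold change 0.80, SE 0.10) and Cxcl5 (1.10, SE 0.19) and the granulocyte growth factor gene Csf3 (0.85, SE 0.06). The gelatinase gene Mmp9 (0.85, SE 0.07) and the metalloreductase gene Steap4 (2.27, SE 0.22) rose too. So did Nfkbiz (0.58, SE 0.07), which encodes a nuclear cofactor for the transcription of IL-17 target genes. Tnfaip3, encoding the NF-kB inhibitor A20, fell by 0.25 (SE 0.05). The list was called higher by camera (adjusted p = 4.16e-15; adjusted p = 0.655 with an estimated correlation), and its median was 0.68 without PBS replicate 2.

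Antimicrobial and acute-phase genes were higher in 13 of 13 tested members, with a median log2 fold change of 0.81, also with the 2 genes at 0 in both PBS libraries set to their bound. Adjusted over the list alone 8 rose, over all genes tested 0 passed, and under the stricter filter 5 of 9 rose. The complement gene C3 rose 1.94-fold from 4628 ± 83.2 to 9002 ± 460 normalized counts, Saa3, encoding an acute-phase serum amyloid A protein, 2.54-fold, the inducible nitric oxide synthase gene Nos2 1.75-fold, and Lbp, encoding a lipopolysaccharide-binding protein, 1.75-fold. The list shares 3 tested genes with the IL-17 targets, Lcn2, Saa3 and S100a8. Camera called it higher (adjusted p = 4.8e-10; adjusted p = 0.271 with an estimated correlation).

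Interferon-response genes were lower in 24 of 27 tested members, with a median log2 fold change of -0.47, and in 20 both rIL17 libraries lay below both PBS libraries, where chance places 16.7% of genes and 4130 of all 20677 tested genes did so. Adjusted over the list alone 17 fell, over all genes tested 0 passed, and under the stricter filter 2 fell. Those were Oasl2 (653 ± 11.1 to 407 ± 24.2) and Ifi27 (1700 ± 22.3 to 1232 ± 25.6), both interferon-induced. Gbp3, an interferon-induced GTPase gene, fell by 0.81, and Irf7 and Irf1, encoding transcription factors of the interferon system, fell by 0.90 and 0.44 on the log2 scale. Camera called the list lower (adjusted p = 4.16e-13; adjusted p = 0.271 with an estimated correlation).

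MHC class I presentation genes were lower in 14 of 17 tested members, with a median log2 fold change of -0.24. Adjusted over the list alone 9 fell, over all genes tested 0 passed, and under the stricter filter only Tapbp fell. Tapbp, encoding the peptide-loading chaperone tapasin, fell from 4500 ± 11.3 to 3220 ± 52.9 normalized counts, and the immunoproteasome genes Psmb8 and Psmb10 fell by 0.38 and 0.42 on the log2 scale. H2-Q4 fell by 0.40, a value that is uncertain because near-identical H2 genes can share reads. B2m, the light chain of MHC class I, had 12797 normalized counts in PBS and 13269 in rIL17 and did not pass. Camera called the list lower (adjusted p = 7.09e-07; adjusted p = 0.348 with an estimated correlation).

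**Figure D1:**
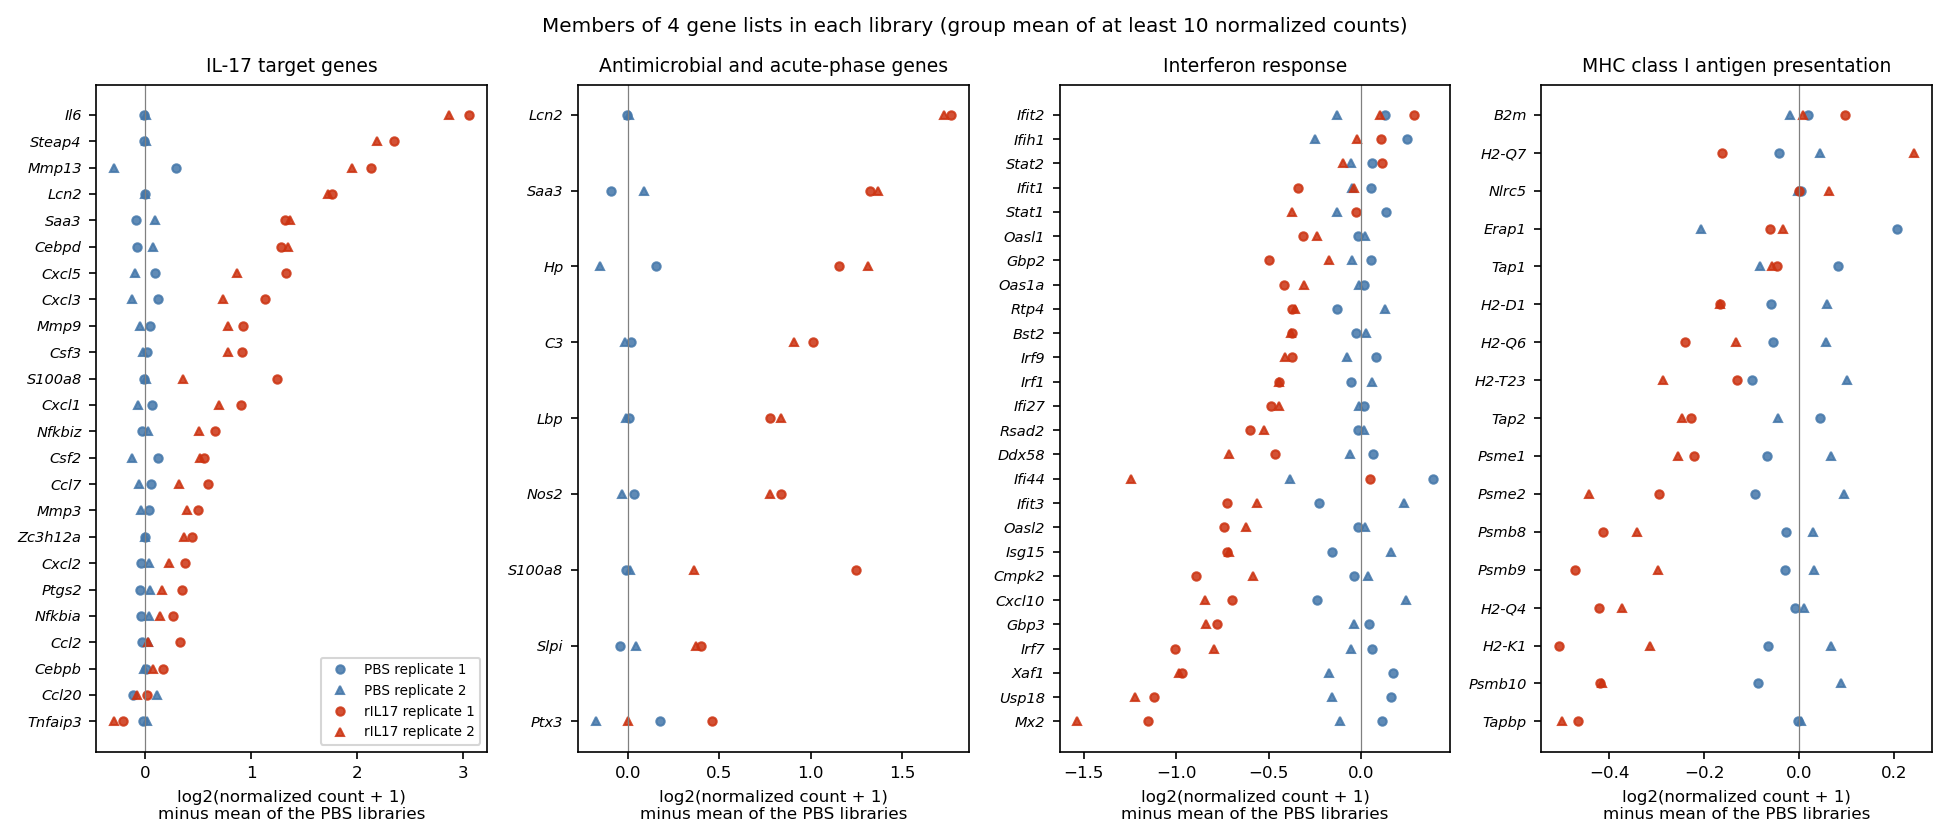
Each row is a gene and each point a library, PBS in blue and rIL17 in red, circles for replicate 1 and triangles for replicate 2; the x axis gives log2(normalized count + 1) minus the mean of both PBS libraries, for members with a group mean of at least 10 normalized counts. Lcn2 lies 1.75 above PBS on average, Oasl2 0.68 below and Tapbp 0.48 below, while Tnfaip3 is the IL-17 target with the most negative mean difference.

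Spp1, the osteopontin gene (ENSMUSG00000029304, mm10 chromosome 5, 104435118 to 104441050, plus strand), had 44188 ± 2070 normalized counts in PBS and 53279 ± 3070 in rIL17. It was higher in both rIL17 libraries than in both PBS libraries, as were 25.4% of all tested genes, where chance places 16.7%. The ratio was 1.21-fold (log2 fold change 0.27, SE 0.07, 95% confidence interval 0.07 to 0.47). The difference did not pass in limma over all genes tested (adjusted p = 0.373, and 0.155 under the stricter filter), and had an adjusted p of 0.0496 over the list of macrophage growth and recruitment factors alone. With robust shrinkage the limma adjusted p was 0.0494. With each library left out in turn, the log2 fold change ran from 0.21 to 0.33. Whether Spp1 passed under the stricter filter then changed with the library left out, since a group of 1 library takes its spread from the other group alone. The Spp1 transcript has a GC content of 43.3%, and with the GC correction the log2 fold change was 0.09 (adjusted p = 0.523). In the list of osteopontin and its receptors, 4 of 9 tested members were higher and 0 passed adjusted over the list alone or over all genes (camera adjusted p = 0.922); Cd44, a receptor of osteopontin, had a log2 fold change of 0.19. In the list of mineralised-matrix and SIBLING genes, the family that includes osteopontin, 0 of 10 passed by either adjustment (camera adjusted p = 0.922).

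The IL-17 receptor and its adaptors showed 0 genes passing by either adjustment among 19 tested (camera adjusted p = 0.922). Il17ra had 1207 ± 50.7 normalized counts in PBS and 1162 ± 110 in rIL17 (log2 fold change -0.06, SE 0.09, adjusted p = 0.788), a sign that turned without rIL17 replicate 1 (0.04). Il17rc had a log2 fold change of -0.13 (adjusted p = 0.493). Traf3ip2, encoding the adaptor Act1, had 0.10 (adjusted p = 0.688) and 0 without rIL17 replicate 2.

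Among macrophage growth and recruitment factors, adjusted over the list alone 5 of 17 tested genes rose and 3 fell, over all genes 0 passed, and under the stricter filter Csf3 rose and Csf1 fell. Csf1 (chromosome 3) had a log2 fold change of -0.70 (SE 0.06 and adjusted p = 0.0114 under the stricter filter, SE 0.04 and adjusted p = 0.25 over all genes tested). Il34, which encodes the other ligand of the M-CSF receptor, fell by 0.59, and the chemokine gene Cx3cl1 by 0.36 on the log2 scale. Csf2, encoding GM-CSF, rose by 0.54, and Spp1 was among the 5, just below the threshold. Spp1 did not pass over the other lists that hold it, and its log2 fold change of 0.27 was 0.09 with the GC correction. The list as a whole was not called by camera (adjusted p = 0.956).

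NF-kB pathway and feedback genes went both ways: adjusted over the list alone 3 rose and 6 fell of 20, over all genes 0 passed, and under the stricter filter Bcl3 and Ier3 rose and Icam1 and Nfkbie fell. Icam1, encoding an adhesion molecule for leukocytes, went from 639 ± 17.9 to 283 ± 25.3 normalized counts, and Bcl3, encoding an atypical IkB protein, from 769 ± 8.06 to 1374 ± 0.148. Nfkbie, which encodes an NF-kB inhibitor, fell by 0.59 and Ier3, an early-response gene, rose by 0.73 on the log2 scale. Chemokines likewise had 3 that rose (Cxcl1, Cxcl5 and Cxcl3) and Cx3cl1 that fell among 18 tested, adjusted over the list alone, and 0 over all genes. Matrix proteases and inhibitors had 5 that rose and 1 that fell among 22, adjusted over the list alone, and 0 over all genes. Besides Mmp13 and Mmp9 they included Serpine2, a protease inhibitor gene (rose 1.45-fold), and Plau, encoding urokinase (log2 fold change -0.51). Camera called none of these 3 lists (adjusted p = 0.53, 0.65 and 0.583).

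**Figure D2:**
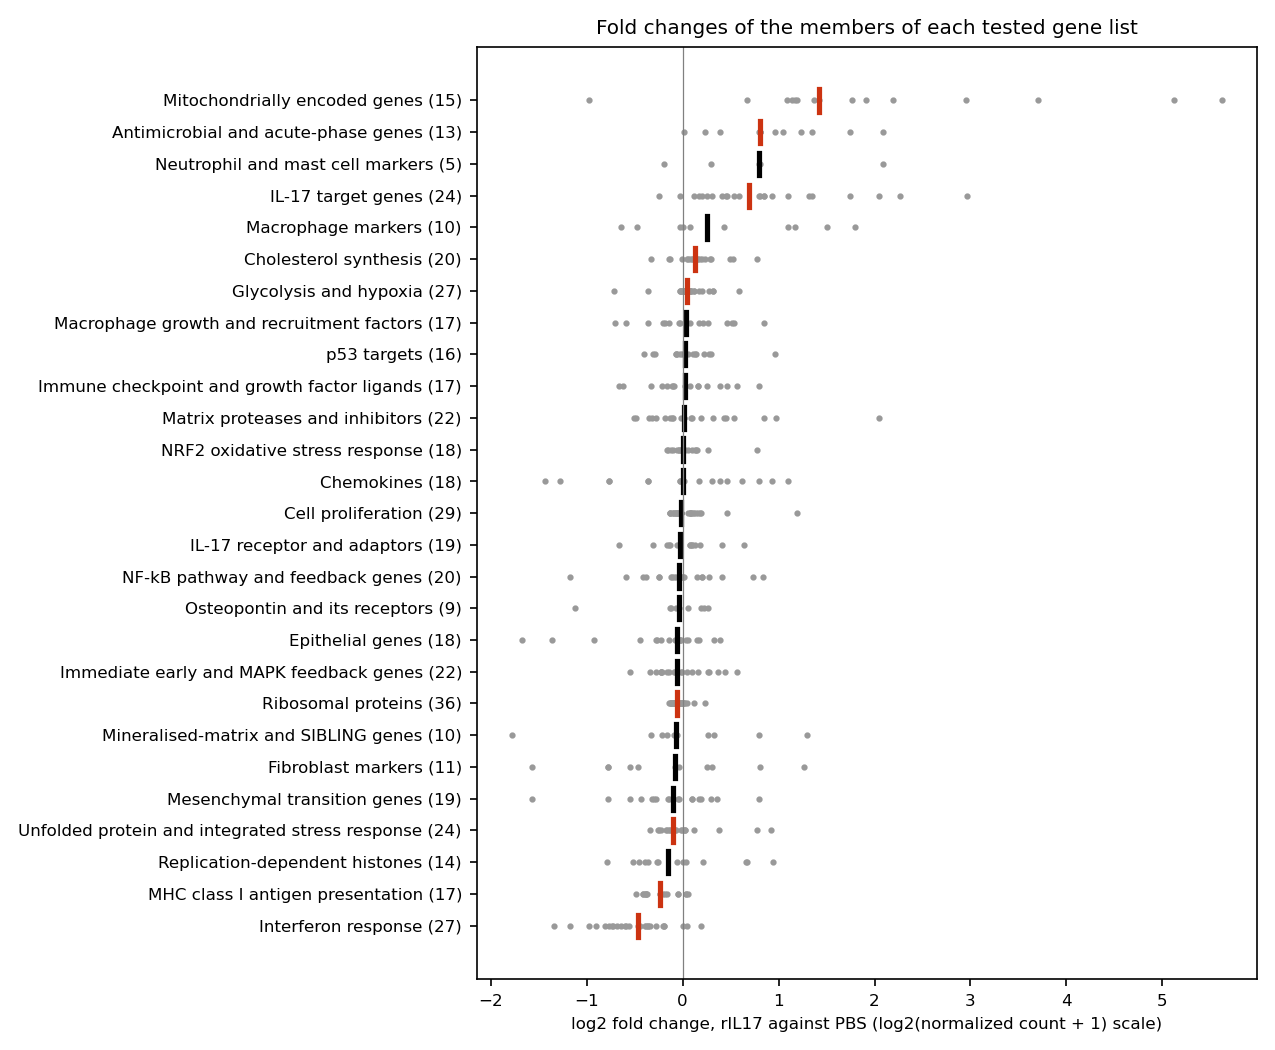
Each grey point is the log2 fold change (rIL17 against PBS) of 1 tested gene, each bar the median of its list, red where camera called the list at an adjusted p below 0.05 with the preset correlation, and the number tested stands in brackets; the x axis is on the log2(normalized count + 1) scale. The medians of the IL-17 target and interferon lists lie at 0.69 and -0.47.

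The 15 mitochondrially encoded genes had a median log2 fold change of 1.42, and 14 were higher in rIL17. Adjusted over the list alone 5 rose, and over all genes 0 passed. Under the stricter filter 2 rose, mt-Nd6 and mt-Nd3. Whether mitochondrial genes share reads with nuclear copies, such as the mitochondrial-like pseudogene Gm28438 on chromosome 1, was not tested. mt-Nd6, a subunit gene of respiratory complex I, had 182 and 50 normalized counts in the PBS libraries and 3602 and 3118 in the rIL17 libraries. mt-Nd2, of the same complex, had 5912 and 277 in PBS and 20682 and 13446 in rIL17 and did not pass. The median difference between the PBS libraries themselves was -1.36, replicate 2 minus replicate 1. Camera called the list higher (adjusted p = 5.39e-06; adjusted p = 0.655 with an estimated correlation), with a median of 0.89 without PBS replicate 2 and 0.80 with the GC correction.

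Smaller shifts were called by camera in 4 further lists, and for each list some alternatives ended the call. Glycolysis and hypoxia genes had a median log2 fold change of 0.05 with 20 of 27 higher (adjusted p = 0.0134; adjusted p = 0.899 with an estimated correlation), and -0.001 with upper-quartile scaling; the call ended without PBS replicate 1 (median 0.001) and without rIL17 replicate 2 (0.03). Pfkfb3, a regulator of glycolysis, rose 1.5-fold and Bnip3, a hypoxia-induced gene, 1.25-fold, adjusted over the list alone, and 0 passed over all genes. Cholesterol synthesis genes had a median of 0.13 with 16 of 20 higher (adjusted p = 0.0213; adjusted p = 0.655 with an estimated correlation); Sc5d rose and Dhcr7 fell, both enzymes of the late pathway, adjusted over the list alone, and 0 passed over all genes. That call ended without any 1 of the 4 libraries, with medians of 0.10 to 0.16. Genes of the unfolded protein and integrated stress response had a median of -0.10 with 17 of 24 lower (adjusted p = 0.0194; adjusted p = 0.607 with an estimated correlation), and 0 passed by either adjustment; Chac1 had a log2 fold change of -0.25 and Slc7a11 of 0.77. The median was -0.05 without PBS replicate 2 (adjusted p = 0.0794), and the call also ended without PBS replicate 1 (-0.11) and without rIL17 replicate 2 (-0.07). Ribosomal protein genes had a median of -0.06 with 30 of 36 lower (adjusted p = 0.0194; adjusted p = 0.899 with an estimated correlation), and 0 passed by either adjustment. Between the PBS libraries the ribosomal median differed by 0.16, and without PBS replicate 2 the list had a median of 0.02 (adjusted p = 0.641). The call also ended without either rIL17 library (adjusted p = 0.109 and 0.177).

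The other lists were not called by camera. Immediate early and MAPK feedback genes (adjusted p = 0.197) had Dusp6 rising by 0.37 and Fosl1 falling by 0.28 among 22, adjusted over the list alone, and 0 over all genes. Immune checkpoint and growth factor ligands (adjusted p = 0.952) had Tgfa and Areg, ligands of the EGF receptor, rising by 0.46 and 0.26 and Pdgfb falling by 0.62 among 17, adjusted over the list alone, and 0 over all genes. For cell proliferation (adjusted p = 0.922), epithelial genes (0.0732), mesenchymal transition genes (0.338), p53 targets (0.797), the NRF2 oxidative stress response (0.928), replication-dependent histones (0.583) and fibroblast markers (0.733), 0 genes passed adjusted over the list alone or over all genes. The proliferation gene Mki67 had a log2 fold change of -0.13, and the epithelial keratin genes Krt8 and Krt18 had -0.26 and -0.27. Macrophage markers (0.293) and neutrophil and mast cell markers (0.248) likewise had 0 passing genes; Ptprc, the pan-leukocyte gene, was at 0 in both PBS libraries and at 3.02 and 2.01 normalized counts in the rIL17 libraries. Their medians of 0.26 and 0.80 became 0.003 and 0.23 with genes at 0 in a whole group set to their bound. T and B lymphocyte markers had 4 tested members and were not tested as a list. The sign of the median differed from that of the mean or of camera for chemokines, IL-17 receptor and adaptors, mineralised-matrix genes, cell proliferation and checkpoint ligands.

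Over all 20677 genes, limma called 0 at an adjusted p below 0.05, and so 0 at 2-fold or more; 2642 had an unadjusted p below 0.05, the smallest adjusted p was 0.0848 for Lcn2, and limma-voom called 1 gene, Lcn2 (adjusted p = 0.00477). With the stricter filter, 12515 genes were tested and 101 passed, 78 higher and 23 lower in rIL17, of which 39 and 5 differed at least 2-fold. That count changed strongly with the library left out, falling without either rIL17 library and rising without either PBS library. A group of 1 library takes its spread from the other group alone, and the rIL17 libraries lay closer together than the PBS libraries. Chosen after the values were seen, the genes with the largest changes under the stricter filter included, besides Il6, Csf1, Icam1, Oasl2 and the mitochondrial genes, P2ry6, a nucleotide receptor gene (17.3 ± 1.93 to 119 ± 33.2 normalized counts), Epha1, an ephrin receptor gene (538 ± 3.01 to 281 ± 2.37), and Cd74, the MHC class II invariant chain (163 ± 4.73 to 74.3 ± 7.22). Apol9a and Apol9b fell by 0.67 and 0.78, Hmgn2 by 2.16 and Entpd4b by 2.78 on the log2 scale; these genes have near-identical copies or pseudogenes, so their counts are uncertain. In the rising direction they included 2 gene models that can share reads in the same way, the mitochondrial-like pseudogene Gm28438 and the pseudogene Gm13230.

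The libraries also differed along transcript GC content. In a principal component analysis of the 12515 genes, the first component held 72.3% of the variance, with PBS replicate 2 at -36.5, PBS replicate 1 at -5.2 and the rIL17 libraries at 24 and 17.7. For the 729 genes with a GC content below 40%, PBS replicate 2 lay 0.47 below PBS replicate 1 at the median, and the group difference (rIL17 minus PBS) was 0.54, or 0.29 without PBS replicate 2. For the 512 genes at 60% or more, PBS replicate 2 lay 0.08 above PBS replicate 1, and the group difference was -0.07, or -0.02 without PBS replicate 2. The medians of the IL-17 target, antimicrobial, interferon and MHC class I lists with the GC correction were 0.64, 0.87, -0.41 and -0.25.

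**Figure D3:**
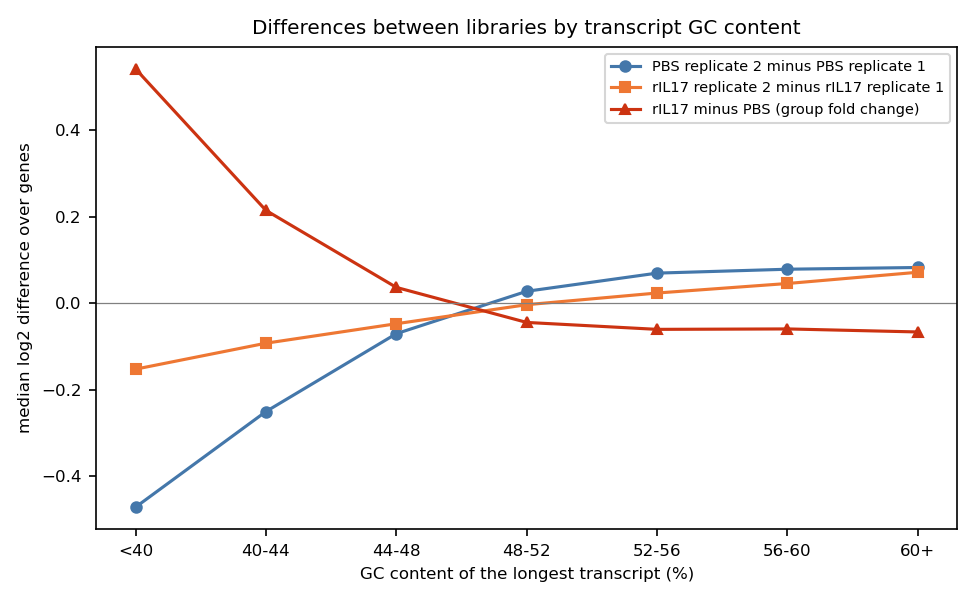
Median log2 difference over genes (y axis) by GC content of the longest transcript in percent (x axis), for PBS replicate 2 minus replicate 1 (blue circles), rIL17 replicate 2 minus replicate 1 (orange squares) and the group fold change (red triangles), over the genes passing the stricter filter. Below 40% GC the medians are -0.47, -0.15 and 0.54, and from 60% they are 0.08, 0.07 and -0.07.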

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

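The count of genes changed rested on the filter, on the scaling, on the correction for GC content and on how the spread was shrunk. Against 0 genes, upper-quartile scaling gave 1 and limma-voom 1 (Lcn2 in both), the stricter filter 101, and, chosen after seeing the data, robust shrinkage 268, total-count scaling 24, the GC correction 110 and the replicate block with the GC correction 97. At 2-fold or more these counts were 1, 1, 44, 77, 13, 27 and 27. No filter, a pseudocount of 0.1, mitochondrial genes left out, quantile normalization, an adjusted p below 0.01, treat and each library left out kept 0. Prior degrees of freedom were 1.63 with the filter used and 4.37 with the stricter one. Of the 101 genes, 76 were also called with the GC correction and 98 with robust shrinkage without the stricter filter. Within the stricter filter, combinations chosen after seeing the data called 168 genes (upper-quartile scaling), 191 (limma-voom), 153 (robust shrinkage), 154 (total-count scaling), 320 (GC correction), 1032 (replicate block) and 615 (replicate block with GC correction), and 1 to 2773 with a library left out; 94 or more of the 101 were among the calls except without either rIL17 library, where 1 was. With 1 library left in a group, it is assumed to vary like the other group. Same-numbered libraries had deviations correlated at 0.157 over 12515 genes, and the labels do not say that numbers pair libraries; the replicate block alone called 0 of 20677 genes and left 9 gene lists called.

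The count of 9 called lists became 0 with an estimated correlation and 5 with fry (IL-17 targets, antimicrobial, interferon, MHC class I and the stress response), and 6 to 9 otherwise. The first 4 of these and the mitochondrial list kept their camera call under each other alternative run that held them, with medians of 0.51 to 0.78, 0.79 to 0.96, -0.52 to -0.41, -0.31 to -0.23 and 0.80 to 2.39. The glycolysis, stress response, cholesterol and ribosomal lists lost theirs under some. The ribosomal list turned to 0.016 without PBS replicate 2, with a range of -0.13 to 0.016 over the libraries left out. Il17ra ran from -0.16 to 0.04 and Traf3ip2 from 0 to 0.2 over the libraries left out; neither passed. Over all genes tested, Spp1 passed in limma with robust shrinkage (0.27, adjusted p = 0.0494). It also passed in 3 of 13 combinations with the stricter filter: with the replicate block (adjusted p = 0.0418), without PBS replicate 1 and without PBS replicate 2. Its log2 fold change ranged from 0.09 to 0.33. Without a PBS library the spread came from the rIL17 pair alone, which lay closer together (chi-square 4.01 per gene, against 15.59 between the PBS libraries). The passes of Spp1 without a PBS library therefore do not measure the spread between PBS libraries. Without a rIL17 library the spread came from the PBS pair alone. Leaving out PBS replicate 2 or correcting for GC content also acts on the difference between the PBS libraries. The cause of the other moves was not tested. Not run were the alternatives made for raw counts (other count-based scalings, a negative binomial test and its threshold test), since limma had been set beforehand for a normalized table. The reads recovered from the steps could have served for them, so how many genes they would call is not known. Depth limits genes near 3 normalized counts, where a count of 0 in a library cannot be told from low expression.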

Other observations

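The tests below were chosen after the results were seen; for the pair on zinc-finger genes, the outcomes expected either way were written before the values they measure were seen. Several genes outside the fixed lists, named after their values were seen, also rose under the stricter filter. The selectin genes Selp and Sele, which encode adhesion receptors best known from endothelium, had 1440 ± 109 and 402 ± 6.61 normalized counts in PBS and 3504 ± 10.1 and 738 ± 45.2 in rIL17 (SD, n = 2; limma adjusted p = 0.00547 and 0.0222). Socs3, a feedback inhibitor of cytokine receptors that signal through JAK kinases, rose 1.75-fold, Osmr, encoding a receptor chain for oncostatin M, 2.40-fold, and Pim2, a kinase gene induced by cytokines, 2.86-fold. Prss12, a secreted serine protease gene, went from 106 ± 22.7 to 445 ± 23.4. In the other direction, Gpnmb, a transmembrane glycoprotein gene, fell from 3712 ± 129 to 2757 ± 47.3.

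Lower interferon and MHC class I genes in rIL17 formed a pattern over 44 genes, with a median log2 difference of -0.38. If the GC-linked difference between libraries were the whole cause, the median would move to 0 with the GC correction, but it stayed at -0.34 (95% bootstrap interval over genes -0.38 to -0.31). The bootstrap resampled genes, not libraries, so its interval does not measure the spread between libraries. For leukocytes in the PBS cultures to be the cause, leukocyte markers would have to fall with the pattern, but of 19 tested markers of macrophages, lymphocytes, neutrophils and mast cells 13 were higher and 6 lower in rIL17 on the log2 scale, the higher ones including Lck (87.4 normalized counts in PBS, 99.9 in rIL17) and Cd28 (19.7 and 25.6), and the 4 whose mean normalized count was lower dropped by 6.33 in all. That is 0.072% of the summed drop of 8852 over the 44 genes. The treatment and a difference in culture state between the groups both stay open and were not tested.

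Mitochondrial transcripts stayed higher in rIL17 after the GC correction, with a list median of 0.80 (interval 0.71 to 2.65). Without PBS replicate 2 the median was 0.89 (0.5 to 1.5), so neither step alone removed the difference. The correction treats all genes at the lowest GC contents alike, which limits how far it can move such genes. It therefore cannot decide whether the rest of the mitochondrial difference is GC-linked, and a GC-linked cause stays open. The intervals for mitochondrial genes also come from resampling genes and do not measure the spread between libraries. Reads counted on the opposite strand would leave plus-strand genes alone, but 17 plus-strand mitochondrial genes had a median of 1.91 (1.19 to 3.70), beside 4.34 over 4 minus-strand genes. The median difference between the PBS libraries was 95.9% of that between the groups, so mitochondrial RNA that varies from library to library stays open as a candidate explanation. A response of the cells stays open too and was not tested.

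Of 307 tested zinc-finger genes, a group noticed among the called genes, 199 were higher in rIL17 with a median log2 difference of 0.14, and 8 were among the 101 genes that passed under the stricter filter. Their median GC content was 44.6%, against 49.7% over the genes passing that filter. The median was 0.05 both with the GC correction, which left 33.6% of it, and without PBS replicate 2, which left 36.8%. The shift of the median over the 307 genes may therefore come largely from the low-GC deficit of that library. Part of the median remained in both tests, and an effect of the treatment on these genes was not excluded. The 8 called genes, which were selected for their differences, still passed in limma with the stricter filter and the GC correction. Their log2 fold changes then ran from 1.05 (Zfp345, 1.53 uncorrected) to 2.53 (Zfp758, 3.15 uncorrected). The correction treats all genes at the lowest GC contents alike, so passing it does not exclude a GC-linked part. Some of these genes lie side by side, such as Zfp944 and Zfp758 on chromosome 17. Whether related zinc-finger genes share reads was not tested, so their counts are uncertain.

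Gapdh, a member of the glycolysis and hypoxia list often used as a reference gene and named here after its values were seen, had 422 and 4374 normalized counts in the PBS libraries and 1180 and 583 in the rIL17 libraries. Whether its reads are shared with near-identical copies or pseudogenes was not tested. Its counts are therefore uncertain and need not reflect a change of the gene's RNA.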
